A study of Homo sapiens with 6 samples.

How the data were processed

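RNA-seq was measured in HaCaT cells, an immortalised human keratinocyte line, in 2 groups of 3 samples each: wild-type cells and cells in which BCL11A, a zinc-finger transcriptional repressor, had been knocked out. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit and purified on AMPure XP beads. Groups and replicate numbers were taken from the sample titles, which give the genotype. The labels do not say how the knockout was made, whether the cells came from 1 clone, or whether the 3 samples of a group were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. No label mentions UVB exposure of the sequenced cells.

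The authors deposited raw counts per gene symbol in 1 table with a column for each of the 6 samples. Trimmomatic, HTSeq and the hg38 build are named in the submitters' processing notes, without versions. The aligner, the gene annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping or antisense partner cannot be told apart. Counts of genes with near-identical copies are uncertain for the same reason, since it is not known how reads that fit several genes were treated.

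The deposited table of counts had 19932 rows, of which 5050 were at 0 in every library. In 27 rows the symbol had been turned into a calendar date. Those rows held 0.171% of the counts, stayed in the library totals and the tests, and are not named. Total counts ran from 12677617 to 14109834 per library. The intervals and floors given with the values cover counting error and the spread between libraries only, because reads without molecular identifiers are not independent molecules. A gene at 0 in a whole group was compared with a floor of 3 counts over its 3 libraries together.

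Gene tests were run in R 4.3.3 with edgeR 4.0.16 on the counts as deposited. Genes were filtered with filterByExpr at its defaults, which left 11388 tested genes, and libraries were scaled by TMM. The quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) compared knockout with wild type over all 6 libraries with no covariate. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are knockout minus wild type. Standard errors were derived from the fold change and its quasi-likelihood F statistic. CPM values are scaled to the TMM-adjusted library size, and ± gives the SD over the 3 libraries of a group unless a standard error (SE) is named.

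Log2 CPM with a prior count of 2 was used for correlations between libraries and for the principal components. Gene lists were tested with camera (limma 3.58.1) on the filtered counts and the dispersions of the edgeR fit. The preset inter-gene correlation was 0.01, with Benjamini-Hochberg adjustment over the 30 lists with at least 3 tested members. The same lists were tested with an estimated correlation and with fry. Fry asks whether the genes of a list move on balance in 1 direction, without comparing them with other genes. The 34 lists, the tests and the rule for named genes were fixed before the data were examined. The rule named BCL11A, the 10 largest increases and 10 largest decreases among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, and from each list up to 2 called members per direction with the smallest adjusted p. It also named the most expressed member of a list with no called member, and SQSTM1, MAP1LC3B, BECN1, ATG5 and ATG7 whatever their values. Members named beyond this rule, to spell out small counts or to give context, were chosen after their values were seen. A few genes that the rule names are not reported here.

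Positions were taken from the RefSeq annotation of GRCh38, the build that the notes name as hg38, and were found for 99.2% of the tested genes. Chromosome arms were divided at approximate centromere positions, and arms with at least 90 tested genes were summarised by the median log2 fold change. GC content and length came from GENCODE transcripts and were available for 99.9% of the tested genes.

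The gene test, the list test and the arm medians were tested on simulated data for the knockout against wild-type comparison, drawn from the real libraries' means and sizes. On 11318 simulated genes the gene test recovered 91% of genes changed by a log2 fold of 1 and 47.5% of those changed by 0.4. Of its calls, 6.12% were on unchanged genes. Far fewer genes were changed in the simulation than were called in the data, so these shares may differ there. The planted list was called and 0 other lists were. Simulated genes were drawn independently of each other, so this did not test the effect of correlation between genes. An arm planted at -0.4 was recovered at -0.39.

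Alternatives were median-ratio (RLE) and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, omission of the mitochondrially encoded genes, the replicate number as a block, omission of each library in turn, DESeq2 1.42.0, limma-voom, an estimated correlation and fry. A further setting, which left out the genes of the long arm of chromosome 1, was chosen after seeing the data.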

Results

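Gene expression was measured by RNA-seq in 3 wild-type and 3 BCL11A knockout samples of HaCaT cells, an immortalised line of human epidermal keratinocytes. Library totals lay between 12677617 and 14109834 counts, and depth was similar in both groups. Across genes, log2 CPM correlated at 0.989 to 0.992 between libraries of the same genotype and at 0.976 to 0.982 between genotypes. No libraries were near-duplicates, since counts of same-genotype pairs differed by more than sampling noise (chi-square per degree of freedom 4.16 to 11.8). Wild-type replicate 3 stood apart from the other wild-type libraries, at 10.8 and 11.8 against 4.26 between those, and at -18.1 on the second principal component (15.2% of the variance) against 9.5 and 10.7. The first component (55.3%) separated the genotypes. The comparison asks how loss of BCL11A changes keratinocyte expression, and the study's title links that loss to autophagy and to protection of the epidermis from UVB.

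The transcript of the targeted gene was present at a similar level in both groups. BCL11A (chromosome 2, 60450520 to 60553924, GRCh38) stood at 8.02 ± 0.791 CPM in wild-type and 7.20 ± 0.928 CPM in knockout libraries (SD, n = 3 each). Its individual values were 8.7, 8.21 and 7.15 CPM in wild type and 7.62, 6.14 and 7.84 CPM in knockout. The log2 fold change was -0.16 (SE 0.17, edgeR quasi-likelihood adjusted p = 0.605), which puts the knockout level at 89.7% of wild type with a 95% interval of 69.7% to 115.4%. Counts per gene cannot show a small insertion or deletion that leaves the transcript in place, so this level neither checks nor contradicts the genotype in the labels.

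Knockout cells had several genes at many times the wild-type level and several nearly silent. The largest increase was in DIO2, the deiodinase that activates thyroid hormone, which rose from 8.53 ± 0.837 to 94.8 ± 2.37 CPM (log2 fold change 3.47, SE 0.10, edgeR adjusted p = 2.67e-12). CA9, a hypoxia-induced carbonic anhydrase, rose from 16.1 ± 1.9 to 85.4 ± 4.47 CPM (2.41, SE 0.10, edgeR adjusted p = 4.03e-10). ANXA10, an annexin, and OLFM4, a secreted glycoprotein of epithelia, rose by log2 2.26 and 2.08, to 38.6 and 33.9 CPM. The phosphatase PTPRR (2.29), the secreted semaphorin SEMA3B (1.97), the sulfatase SULF1 (2.22), RARRES3 (2.16), cytidine deaminase CDA (1.87) and PPFIA4 (2.45) completed the 10 largest increases.

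Among the decreases, C16orf54 (chromosome 16, 29742463 to 29745990) had 0 counts in all 3 knockout libraries against 8.70 ± 0.877 CPM in wild type. Measured against a floor of 3 counts over the 3 knockout libraries, it was at least 119-fold lower (edgeR adjusted p = 7.45e-08). The ephrin receptor EPHA3 fell from 15.8 ± 1.37 to 0.752 ± 0.0972 CPM (log2 fold change -4.37, SE 0.22, edgeR adjusted p = 2.95e-09). DPYSL3, a cytoskeleton-associated protein, fell from 20.9 to 1.97 CPM (-3.40), and FABP4, a fatty acid carrier, from 7.07 to 0.530 CPM (-3.71). GLB1L2 (-3.82), the retinoic acid carrier CRABP2 (-2.94), the heparan sulfate proteoglycan SDC3 (-2.91), the potassium channel subunit KCNS3 (-2.88), the kinase RPS6KA2 (-2.61) and the microfibril protein FBN2 (-2.55) were the other largest decreases. CRABP2 and PPFIA4 lie on the long arm of chromosome 1 (1q), where the median gene was at -0.45.

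Across the 11388 tested genes, 733 were higher and 910 lower in knockout by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, or 14.4% of those tested. At least 2-fold changes numbered 114 higher and 134 lower. The 3 libraries of each group did not overlap for 32% of tested genes, against 10% by chance. Leaving out knockout replicate 3 gave 475 higher and 636 lower genes, and leaving out wild-type replicate 3 gave 690 and 910. Without the genes of 1q the counts were 644 higher and 569 lower.

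**Figure D1:**
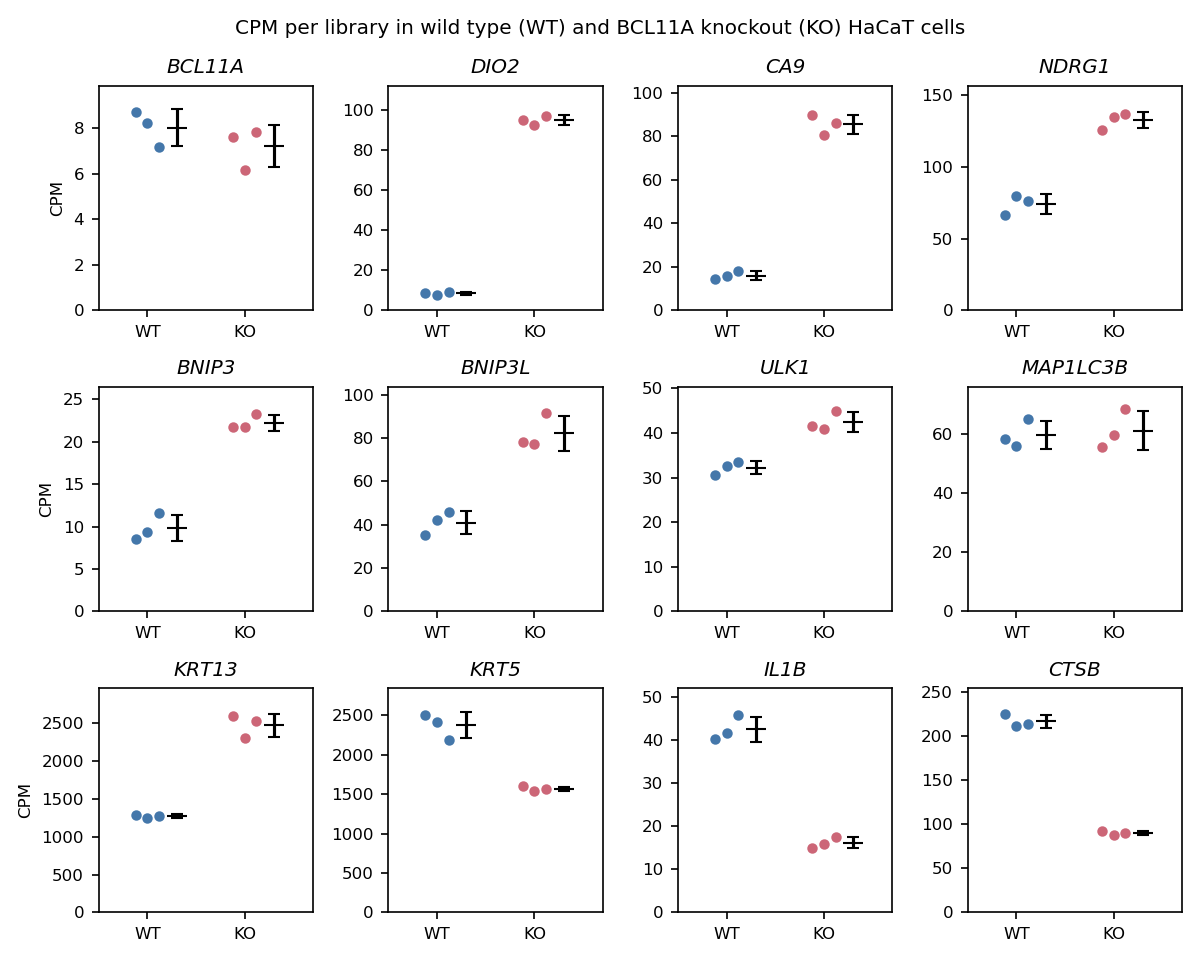
CPM (vertical axis, from 0) of 12 genes in each of the 3 wild-type (WT, blue) and 3 knockout (KO, red) libraries, with the group mean and SD as black bars. BCL11A and MAP1LC3B overlap between the groups, DIO2 and CA9 reach 94.8 and 85.4 CPM in knockout, and KRT5, IL1B and CTSB are lower in knockout.

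Most genes that build autophagosomes did not pass the test, and the few that did were higher in knockout. Of 31 tested members of the autophagy core list, 5 rose, 0 fell and 26 did not pass (5 higher and 0 lower adjusted over the list alone). That share is close to the 14.4% of all tested genes that changed in either direction. The 5 higher members were ULK1, the kinase that starts autophagy, at log2 0.40 (SE 0.09, from 32.2 to 42.5 CPM, edgeR adjusted p = 0.00606), its partner RB1CC1 (0.37), ATG9A (0.32), GABARAPL1 (0.31) and ATG2A (0.25). MAP1LC3B, the source of LC3B, had a log2 fold change of 0.03 (edgeR adjusted p = 0.85), BECN1 -0.06 (0.716), ATG5 -0.06 (0.744) and ATG7 0.13 (0.564). The list's median was 0.06 and camera did not call it (adjusted p = 0.15, and adjusted p = 0.36 with an estimated correlation). Fry, which does not compare a list with other genes, gave an adjusted p = 0.018. The count of 5 became 2, 3 and 3 without wild-type replicates 1, 2 and 3, and 2, 2 and 1 without knockout replicates 1, 2 and 3; ULK1 kept its call each time. With the genes of 1q left out, 2 members were called. ATG2A was not called with DESeq2 or upper-quartile scaling, nor GABARAPL1 with limma-voom or upper-quartile scaling.

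The called genes of selective autophagy are known to act on mitochondria, as are FUNDC1 (log2 -0.29), FKBP8 (0.08) and PHB2 (-0.01), which were not called. The receptor gene BNIP3 went from 9.85 ± 1.58 to 22.2 ± 0.936 CPM (log2 1.17, SE 0.13, edgeR adjusted p = 1.62e-05) and BNIP3L from 41.0 ± 5.33 to 82.2 ± 8.0 CPM (1.01, SE 0.10, edgeR adjusted p = 6.35e-06). The mitochondrial kinase PINK1 rose by 0.43. BNIP3, BNIP3L and PINK1 were the 3 of 14 tested selective autophagy genes that rose, with 0 lower (5 and 0 adjusted over the list alone). The median of the list was 0.04. Camera called the list higher (adjusted p = 0.023; adjusted p = 0.36 with an estimated correlation), but not without knockout replicate 3 (adjusted p = 0.052). SQSTM1, which encodes the autophagy substrate p62, had 2 to 15 counts per library and was not tested. The table also held almost no counts for genes that every cell uses, such as RPL7A (0 to 4) and RPS18 (0 to 3), so no expression level is drawn from such values.

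The called lysosomal genes were all lower. CTSB, which encodes the protease cathepsin B, fell from 217 ± 7.26 to 90.2 ± 2.57 CPM (log2 -1.27, SE 0.07, edgeR adjusted p = 7.68e-09), and the proton pump subunit ATP6V1B2 fell slightly (-0.21). In all, 3 of 27 tested members fell and 0 rose (2 lower adjusted over the list alone), while 14.4% of all tested genes changed in either direction. Camera called the list lower (adjusted p = 0.0073, and adjusted p = 0.32 with an estimated correlation). Without knockout replicate 2 CTSB alone was called, and ATP6V1B2 was called in only 1 of the 6 fits with 1 library left out, that without wild-type replicate 3, and not without a filter on low counts. Upstream regulators were mixed, with 2 of 21 higher and 2 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.85): DDIT4, an mTOR inhibitor, rose by 0.53 and the kinase STK11 by 0.30, SESN3 fell by 0.64 and PRKAB2, on 1q, fell by 0.36. STK11 and PRKAB2 each lost their call without wild-type replicate 1 or knockout replicate 1 or 3, and PRKAB2 also without wild-type replicate 2.

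Several keratins were higher in knockout, and some basal and wound-type genes were lower. The list fixed as simple epithelial keratins had 4 of 5 tested members higher (4 adjusted over the list alone). They were the simple keratins KRT8 (0.53), KRT18 (0.44) and KRT19 (0.23), and KRT13, a keratin of mucosal stratified epithelium, from 1267 ± 23.4 to 2473 ± 151 CPM (log2 0.96, SE 0.07, edgeR adjusted p = 7.45e-08). KRT7, the most abundant member, had a log2 fold change of -0.05 (edgeR adjusted p = 0.665). Camera called this list higher (adjusted p = 1.8e-05; adjusted p = 0.32 with an estimated correlation). Genes of the basal layer and hemidesmosome fell in 5 of 13 tested members and rose in 1 (7 and 3 adjusted over the list alone), with KRT5 down from 2372 ± 168 to 1571 ± 29.3 CPM (-0.60), the collagen COL17A1 (-0.64), the laminin chains LAMB3 (-0.33) and LAMA3 (-0.52), and the laminin receptor BCAM up (0.33). Camera called it lower (adjusted p = 0.0014; adjusted p = 0.44 with an estimated correlation). Without wild-type replicate 3 the number lower was 8.

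Wound keratins and alarmins fell in 4 of 7 tested members (4 adjusted over the list alone), namely KRT17 (-1.79), KRT6A (-0.83), S100A9 (-1.64) and S100A2, which went from 541 ± 57.0 to 268 ± 30.7 CPM (-1.02). Camera called the list lower (adjusted p = 8.2e-05; adjusted p = 0.20 with an estimated correlation). Differentiation genes split, with 2 higher and 4 lower of 12 tested (3 and 4 adjusted over the list alone; camera adjusted p = 0.85). The transcription factor OVOL1 (1.29) and the protease KLK7 (1.03) rose, and FLG, the filaggrin gene (-1.16), IVL (-0.94), CSTA (-0.36) and KLK5 (-0.28) fell. FLG had 1041, 849 and 437 counts in wild-type replicates 1 to 3 and 291 to 442 in knockout, and the FLG log2 fold change was -1.44 without wild-type replicate 3. Of the lower genes named here and among the basal genes, LAMB3, S100A9, S100A2, FLG and IVL lie on 1q, and without 1q camera gave adjusted p = 0.027 for the basal and 0.0067 for the wound list. IVL, CSTA, KLK5, KLK7, KRT19 and S100A9 lost their calls in at least 1 fit with 1 library left out, IVL also with limma-voom and KRT19 with upper-quartile scaling or without 1q. Without wild-type replicate 1 or knockout replicate 3 a single differentiation gene was lower. Keratin counts are uncertain because of near-identical copies and pseudogenes: KRT14 had 2 to 5 counts per library.

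Epithelial junction genes rose in 4 and fell in 2 of 19 tested members (5 and 2 adjusted over the list alone; camera adjusted p = 0.17). The tight junction gene CLDN1 (0.53) and the E-cadherin gene CDH1 (0.37, from 234 to 303 CPM) rose with CLDN4 (0.22) and PKP2 (0.23), while the desmosomal DSC3 (-0.38) and PKP1 (-0.41, on 1q) fell. CLDN4 and PKP2 lost their calls without wild-type replicate 1 or 2 or knockout replicate 1 or 3, and CLDN4 also without knockout replicate 2, without 1q or with upper-quartile scaling. In the mesenchymal list 5 of 9 tested members fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0069; adjusted p = 0.32 with an estimated correlation). TAGLN, an actin-binding protein, fell from 17.6 ± 3.94 to 5.00 ± 0.834 CPM (-1.82), and the transcription factor SNAI2 (-0.38), fibronectin FN1 (-0.44), CDH2 (-0.26) and TGFBI (-0.20) fell. FN1 had 52686, 51703 and 36454 counts in wild-type replicates 1 to 3 and 33697 to 38352 in knockout, and the FN1 log2 fold change was -0.59 without wild-type replicate 3. Without wild-type replicate 1 only TAGLN and SNAI2 were called lower, and 3 members were lower without wild-type replicate 2 or knockout replicate 2 or 3. No member was higher (0) without wild-type replicate 1 or knockout replicate 3.

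Camera called none of the lists for p53, repair and apoptosis. Among p53 targets 1 of 24 was higher and 2 were lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.85): DDB2, which recognises UV lesions, rose by 0.32, while PHLDA3 (-0.51, on 1q) and PMAIP1 (-0.41) fell. In nucleotide excision repair, the pathway that removes UV photoproducts, 2 of 21 rose (2 adjusted over the list alone; camera adjusted p = 0.76), DDB2 and the helicase ERCC2 (0.41). Apoptosis regulators gave 3 higher and 4 lower of 25 (4 and 4 adjusted over the list alone; camera adjusted p = 0.85), with the inhibitor BIRC3 up from 17.6 to 34.9 CPM (0.99), BCL2L11 (0.37) and APAF1 (0.29) up, and MCL1 (-0.61, on 1q), CYCS (-0.40), BCL2 (-0.91) and PMAIP1 down. DDB2 lost its call without wild-type replicate 1 or knockout replicate 3, and BCL2, BCL2L11, APAF1 and PMAIP1 lost theirs in at least 1 fit with 1 library left out. BCL2 was also not called with DESeq2 or limma-voom, nor APAF1 without 1q.

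The called inflammatory and antioxidant genes were all lower. IL1B went from 42.5 ± 2.91 to 16.2 ± 1.33 CPM (log2 -1.39, SE 0.10, edgeR adjusted p = 2.57e-07) and IL1A to 7.47 ± 0.516 CPM, 0.415 times its wild-type level (-1.27, SE 0.15, edgeR adjusted p = 2.59e-05), with TNFAIP3 (-0.63), CXCL1 (-0.75) and IL18 (-0.36) also lower. These were 5 of 13 tested members, with 0 higher (7 lower adjusted over the list alone; camera adjusted p = 0.00012; adjusted p = 0.32 with an estimated correlation). Targets of NRF2, the antioxidant transcription factor, fell in 6 of 20 tested members and rose in 0 (8 lower adjusted over the list alone; camera adjusted p = 0.0014; adjusted p = 0.32 with an estimated correlation). They included AKR1C2 (-0.91), whose sequence is close to AKR1C1 (-0.99), thioredoxin TXN (-0.43) and NQO1 (-0.37). CXCL1 and IL18 lost their calls without knockout replicate 2, where 3 inflammatory genes were lower, and IL18 also without wild-type replicate 3 or knockout replicate 1.

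Interferon genes showed no joint direction, with 1 higher and 3 lower of 18 (2 and 4 adjusted over the list alone; camera adjusted p = 0.85). OASL (-0.71), IFI44 (-0.65) and IFIT3 (-0.29) fell and IFIT2 rose (0.32), though IFIT2 lost its call without wild-type replicate 2 or knockout replicate 2 and IFIT3 without wild-type replicate 1 or knockout replicate 1 or 3. Stress-response genes for unfolded protein and amino acid shortage gave 2 higher and 5 lower of 17 (2 and 7 adjusted over the list alone). Amino acid enzymes ASNS (-0.49) and PSAT1 (-0.45), the transporter SLC7A11 (-0.36), CHAC1 (-0.70) and VLDLR (-1.18) fell, and ATF3 (0.69) and DDIT4 rose. Camera did not call that list (adjusted p = 0.29; adjusted p = 0.44 with an estimated correlation), fry did (adjusted p = 0.027), and camera without 1q gave adjusted p = 0.026.

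Hypoxia-induced and glycolytic genes gave the largest number of higher members among the lists tested. Of 17 tested members 11 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.47. EGLN3, an oxygen-sensing hydroxylase, rose from 8.71 to 20.6 CPM (log2 1.24). NDRG1 rose from 74.2 ± 7.07 to 133 ± 5.83 CPM (0.84, SE 0.08, edgeR adjusted p = 3.73e-06). PDK1, a kinase that inhibits pyruvate dehydrogenase, rose from 25.8 to 50.6 CPM (0.97), and lactate dehydrogenase LDHA from 2139 ± 24.3 to 2959 ± 186 CPM (0.47). CA9 and BNIP3 are also on this list. Camera gave an adjusted p = 1.6e-18 and fry 0.00086, but adjusted p = 0.059 with an estimated correlation. Between 9 and 12 members rose when any 1 library was left out.

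Part of the lipid and mitochondrially encoded genes rose. Genes of the cholesterol list rose in 7 and fell in 2 of 20 tested members (9 and 2 adjusted over the list alone), with the synthesis enzyme HMGCS1 (0.31) higher, and the sterol carrier STARD4 (-0.46) and FDPS (-0.30, on 1q) lower. Camera called the list higher (adjusted p = 0.0045; adjusted p = 0.45 with an estimated correlation), while fry gave an adjusted p = 0.061. FDPS lost its call without wild-type replicate 1 or 2 or knockout replicate 2 or 3. In fatty acid and ceramide synthesis 2 of 13 rose (3 adjusted over the list alone; camera adjusted p = 0.18), the desaturase SCD (0.37) and UGCG (0.33), the latter not without wild-type replicate 1 or 2 or knockout replicate 3. Mitochondrially encoded genes took 2.65% ± 0.25 of counts in wild type and 3.12% ± 0.14 in knockout (SD, n = 3 each). Of the 13, 5 rose and 0 fell (8 adjusted over the list alone), led by MT-CO1 (0.37) and MT-ND5 (0.41), with camera adjusted p = 0.0014 (adjusted p = 0.44 with an estimated correlation) and fry adjusted p = 0.061. The number was 9 without wild-type replicate 3 and 3 without wild-type replicate 1.

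Matrix proteases and their inhibitors rose in 6 and fell in 1 of 11 tested members (8 and 1 adjusted over the list alone). TIMP3 rose from 85.1 ± 2.03 to 183 ± 10.6 CPM (2.15-fold, edgeR adjusted p = 5.39e-08), with TIMP2 (0.48), MMP14 (0.31), MMP1 (1.13) and MMP10 (1.62) higher and TIMP1 lower (-0.32). Camera called the list higher (adjusted p = 0.00012; adjusted p = 0.32 with an estimated correlation). TIMP1 was not called without knockout replicate 3, and MMP1 and MMP10 stood at 3.09 and 2.63 CPM in knockout and lost their calls without knockout replicate 1, MMP1 also without wild-type replicate 1 or knockout replicate 3. Immediate early and MAPK target genes rose in 7 and fell in 3 of 19 (10 and 4 adjusted over the list alone), with EGR1 from 109 ± 2.8 to 193 ± 11.7 CPM (0.83), FOS (0.72) and ATF3 (0.69) higher, and FOSL1 (-0.51) and DUSP4 (-0.52) lower. Camera gave an adjusted p = 0.0037 (adjusted p = 0.45 with an estimated correlation), 0.069 without wild-type replicate 2, and fry 0.061. ATF3 lies on 1q. DUSP4 lost its call without wild-type replicate 1 or 3 or knockout replicate 1 or 3, and without wild-type replicate 1 or 3 or knockout replicate 3 FOSL1 alone was lower. Without knockout replicate 3 the number higher was 4.

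Few growth-factor and proliferation genes passed the test. In the Wnt list 3 of 11 rose and 0 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.42): WNT7B (0.47), DKK1 (0.29) and WNT10A (0.38), of which WNT7B alone was called higher without wild-type replicate 1 or knockout replicate 1 or 3. The receptor ERBB3 (0.53) was the 1 of 8 EGFR-family genes that rose (1 and 1 adjusted over the list alone; camera adjusted p = 0.33). Of 24 cell cycle and replication genes 0 rose and 1 fell, CCNE2 (-0.71), with a list median of 0.03 (0 and 1 adjusted over the list alone; camera adjusted p = 0.85). In that list 2 were lower without wild-type replicate 1, without a filter on low counts, without 1q, with upper-quartile scaling, with DESeq2 and with limma-voom, and 1 was higher without wild-type replicate 2 or 3, without a filter and with DESeq2. None of the 12 tested members of the BCL11A paralog and NuRD list passed (0 adjusted over the list alone; camera adjusted p = 0.85); its most expressed member, MTA2, had a log2 fold change of 0.08 (edgeR adjusted p = 0.453). Without wild-type replicate 2 or without a filter, 1 member each of the NuRD, Wnt and EGFR lists was lower, and 1 NuRD member was higher without wild-type replicate 3.

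Markers of other cell types and of RNA content gave few calls. Of the list of globin genes and the carbonic anhydrase gene CA1, markers of the red cell lineage where BCL11A represses fetal globin, 0 of 9 members had enough counts to be tested. Fibroblast, melanocyte and leukocyte markers passed in 0 of 2, 0 of 2 and 0 of 3 tested members, with COL1A1 at 5.76 and 7.93 CPM, MITF at 16.8 and 20.6 and CD68 at 24.9 and 28.2 in wild type and knockout; adjusted over the list alone, 2 fibroblast genes were higher and 0 of the others. Over all genes tested, 1 fibroblast gene was higher without knockout replicate 2 or without a filter. The endothelial cadherin gene CDH5 rose from 49.9 to 71.2 CPM (log2 0.51), 1 of 2 tested endothelial markers (1 adjusted over the list alone). Ribosomal protein genes fell in 1 of 32 tested members (1 adjusted over the list alone, camera adjusted p = 0.42), RPS27 (-0.78), which lies on 1q. Without knockout replicate 1 camera called the ribosomal list lower (adjusted p = 0.03). Of 6 histone genes HIST1H1C rose (0.73; 1 adjusted over the list alone), and camera called the list higher (adjusted p = 0.029; adjusted p = 0.32 with an estimated correlation), but not without wild-type replicate 3 (0.059) or knockout replicate 1 (0.051), or without a filter on low counts (0.069).

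Over the 30 tested lists, camera called 8 higher and 6 lower at the preset correlation. With an estimated correlation it called 0, with 3 lists at an unadjusted p under 0.05, and fry called 13, of which 11 were also camera calls.

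**Figure D2:**
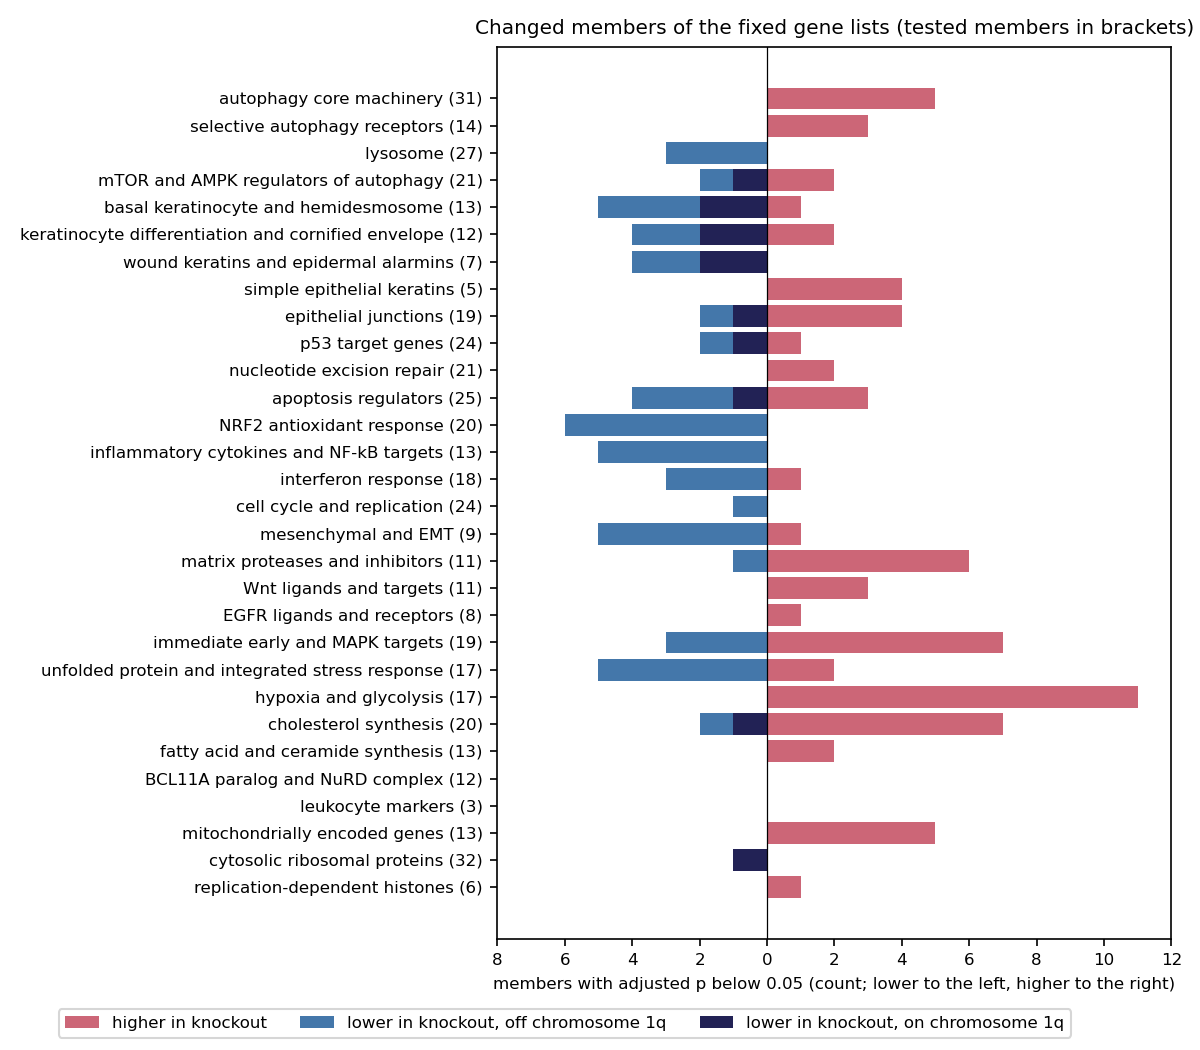
Number of members with an edgeR adjusted p under 0.05 in each fixed gene list with at least 3 tested members (tested members in brackets), higher in knockout to the right and lower to the left, with lower genes on 1q in dark blue. Hypoxia and glycolysis has 11 higher members and the autophagy core 5, and NRF2 targets have 6 lower.

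Genes of 1q were lower in knockout as a block. Of 522 tested genes there, 339 fell and 9 rose, 92.1% had a log2 fold change below 0, and the median was -0.45, or 73.2% of the wild-type level. The arm held 37.3% of all lower genes and 4.6% of tested genes. Its genes took 4.39% ± 0.024 of counts in wild type and 3.23% ± 0.037 in knockout (SD, n = 3 each). The short arm of chromosome 1 had a median of 0.01 over 657 genes, and the medians of all 39 other arms with at least 90 tested genes lay between -0.09 and 0.05. In windows of 31 neighbouring genes the 1q medians ran from -0.76, between FLG and PMVK, to -0.29, between SRGAP2 and ATF3. The arms were examined after other values had been seen, and 1295 changed genes, 724 higher and 571 lower, lay elsewhere or had no position.

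**Figure D3:**
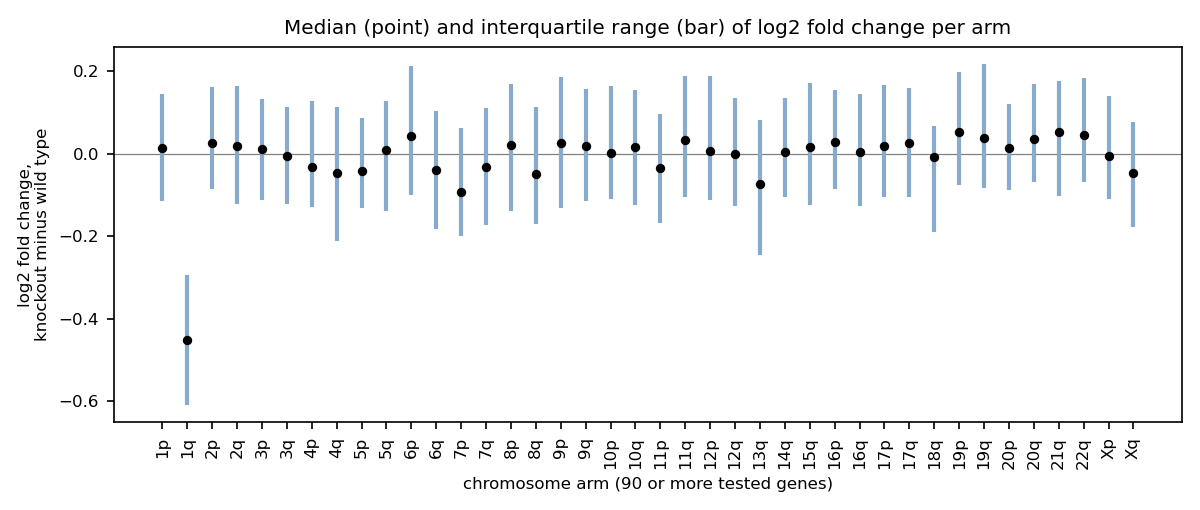
Median (points) and interquartile range (bars) of the log2 fold change, knockout minus wild type, for each chromosome arm with at least 90 tested genes. The long arm of chromosome 1 lies at -0.45 and every other arm between -0.09 and 0.05.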

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

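The setting without the genes of 1q was chosen after the data were seen. BCL11A was not called in any setting, with log2 fold changes from -0.24 to -0.05. The count of higher genes ran from 475 to 740 when 1 library was left out, the lowest without knockout replicate 3, that of lower genes from 636 to 910, and that of genes changed at least 2-fold from 221 to 245; fewer libraries leave less power. Without 1q 644 genes were higher and 569 lower, against 724 and 571 of the original calls that were not on 1q. Of those 1295 calls 1212 were kept, so leaving out 1q also changed calls elsewhere. Of the 1643 changed genes, 1508 kept their call and direction with DESeq2, 1599 with limma-voom, 1627 with RLE and 1615 with upper-quartile scaling, 1630 without a filter and 1083 without knockout replicate 3. With an estimated correlation camera called 0 lists, and between 13 and 14 when 1 library was left out. For the autophagy core list fry gave an adjusted p of 0.018; camera gave 0.093 to 0.21 when 1 library was left out. Of 169 called genes that were followed, 58 lost their call in at least 1 setting, and 0 values turned direction. The labels do not say that replicate numbers pair the samples, so the main test had no block. Deviations of same-numbered samples from their group means correlated at -0.019, 0.144 and 0.005, which does not settle whether they are paired. With the replicate block 859 genes were higher, 997 lower and 247 changed at least 2-fold, and 14 lists were called. The call of BCL2 was lost with the block (edgeR adjusted p = 0.0501), and the cell cycle list had 1 higher and 2 lower members. Small changes may be missed at this depth and sample number. In the simulation 47.5% of changes of log2 0.4 were recovered. It changed far fewer genes than were called in the data, where recovery may differ.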

Other observations

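The tests of gene families, of 1q and of the other arms in this part were chosen only after the results were seen. Of 11 tested matrix metalloproteinases, which cut extracellular matrix, 6 were higher and 0 lower. The higher genes included MMP7, from 12.3 to 24.5 CPM (log2 fold change 1.00, SE 0.12, edgeR adjusted p = 3.65e-05). They also included MMP12, from 0.283 to 1.4 CPM (2.28, SE 0.50, edgeR adjusted p = 0.00526). MMP7, MMP12, MMP1 and MMP10 all lie on 11q, while the higher MMP14 and MMP15 lie on 14q and 16q. Semaphorins, guidance and adhesion signals, were higher in 7 and lower in 3 of 15, with SEMA3B (1.97), SEMA6B (0.89), SEMA3A (0.54) and SEMA4B (0.54) higher, and SEMA5A (-1.17), SEMA3C (-0.40) and SEMA4A (-0.73, on 1q) lower. Mitochondrial ribosomal protein genes of the large subunit were lower in 6 of 49, and MRPL9 (-0.80), MRPL24 (-0.89) and MRPL55 (-0.54) of these lie on 1q. Of 11 NBPF genes, near-identical copies whose reads may be shared, 5 were lower and 9 of the 11 lie on 1q. Among 190 families defined by symbol root with at least 8 tested members, camera called these 4 (adjusted p = 0.0087 for the MMP root, whose 12 members include the opposite-strand gene MMP24OS, 0.03 for SEMA, 0.032 for MRPL and 0.027 for NBPF), and 0 families with an estimated correlation (adjusted p = 0.99). Of the called members, 3 of 6 MMP genes kept their call without knockout replicate 1, 3 of 6 MRPL genes without wild-type replicate 1 or knockout replicate 2, and of 5 NBPF genes 2 without wild-type replicate 1 and 3 without knockout replicate 1.

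The first pattern is the set of 1643 changed genes with its block of lower genes on 1q. A trend in GC content and length explained 2.17% of the variance of the log2 fold changes, which argues against a strong trend. That variance includes noise between libraries, so a weaker trend among the changed genes is not excluded. After removal of a trend in GC content, length and expression the 1q median was -0.46. That argues against such trends as the source of the 1q block. The 1q median was at most -0.43 in the lower, middle and upper ranges of expression alike and its spread (median absolute deviation 0.23) lay within that of the other arms (0.16 to 0.24), consistent with fewer copies of the arm in the knockout than in the wild-type cells; 3 copies against 4 would give -0.42, and whether such a difference arose before, during or without loss of BCL11A was not tested. Arms with a median beyond 0.2 held 21.2% of changed genes, between the bounds of 10% and 50% set beforehand. No other arm with at least 90 tested genes had a median beyond 0.09 in size. A whole-arm shift could thus explain the typical fall on 1q. The 1q medians in windows of 31 genes ran from -0.76 (FLG to PMVK) to -0.29 (SRGAP2 to ATF3). Whether a single shift of the arm accounts for that range was not tested. No shift as large was seen on the other arms with at least 90 tested genes. Their medians do not exclude a smaller shift or a change of a segment. On 7p 22 genes were lower and 3 higher, and windows of 31 neighbouring genes off 1q ran from -0.19 on 13q to 0.25 on 19q. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes, the real one with 1643 (highest other 0). With 10 splits a share under 0.05 cannot be reached. Every other split mixes the genotypes, so a genotype difference adds to the spread within its groups. The 0 calls there therefore allow no conclusion about chance.

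The second pattern is C16orf54 at 0 counts in every knockout library. At the wild-type level 358 counts would have been seen there, which argues against depth. The 22 tested genes that start within 500 kb had a median log2 fold change of 0.09, with 0 lower and 2 higher, which argues against loss of a chromosomal segment that covers them. A smaller deletion, silencing of the gene in the cells that founded the knockout line, or regulation by BCL11A may account for it, and these stay open because counts per gene do not separate them.

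The last pattern is the rise of CA9 and SLC2A3, a glucose transporter that went from 4.41 to 15.5 CPM (log2 fold change 1.81, SE 0.17, edgeR adjusted p = 2.05e-06). The other 16 tested members of the hypoxia and glycolysis list had a median of 0.46 (quartiles 0.23 and 0.67) and 10 of them were higher, consistent with a broad hypoxia-type programme rather than a change of CA9 alone. The 24 cell cycle genes had a median of 0.03 (quartiles -0.06 and 0.10), which argues against denser, less proliferative knockout cultures as the cause. Cell cycle genes do not measure density, so denser cultures with unchanged proliferation are not excluded. Oxygen or medium differences between cultures with little effect on cell cycle genes, and an effect of BCL11A itself, may each explain the rise and were not tested. BNIP3 belongs to this list and to the selective autophagy list, so its rise is not independent evidence for either.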
